A study of Homo sapiens with 22 samples.

How the data were processed

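Total RNA of the human lines BEAS-2B and NCI-H1299 was measured by RNA-seq in 22 libraries that formed 8 groups. Per the submitters' processing notes, reads were handled with Trim Galore 0.6.6, STAR, featureCounts and edgeR on build hg38. The versions of the last 3 tools, the annotation release, the strand setting and the treatment of reads with several positions were not given in the sources used here. Per the labels' protocols, RNA was taken up in Trizol and libraries followed standard Illumina protocols. The authors deposited RPKM values, read counts scaled by gene length and library depth, in 4 tables, each with the treated and control libraries of 1 comparison. Of these, 3 tables listed 60617 entries and the table of the LCDR knockdown listed 56609.

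The length behind the RPKM values was tested on the values themselves. RPKM multiplied by the genomic span of each gene in GENCODE 29, introns included, and by 1 total per library gave whole reads, within 0.02 reads, for 83.7 to 85.8% of the values below 20 reads. These reads summed to 98.7 to 99.1% of the library totals so obtained. RPKM was thus scaled by gene span and by reads in genes, and genes with long introns carry low values, so a filter on RPKM bears harder on them. A span was found for 95.3% of the names in 3 tables and for 98.6% in the LCDR table. Names listed more than once were left out (1683 entries in 3 tables and 4 in the LCDR table), as were 23 entries in each table whose names had turned into dates. All left-out entries held 0.02 to 0.24% of the summed RPKM of a library. The LCDR table held 0 names that start with RF, and the other tables held 1865.

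The recovered totals ran from 20.6 to 54.3 M (megareads) in genes per library. Read ratios of single genes between groups have exact binomial 95% intervals, which cover counting error only, and a group with 0 reads was set at a floor of 3 reads over the group. LCDR was matched through its Ensembl identifier and its older symbol LINC00653, under which the tables list it, and coordinates are those of GENCODE 29 on GRCh38.

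Each comparison was fitted within its own table on log2(RPKM + 0.5), for genes with an RPKM of at least 0.5 in as many libraries as the smaller group held. The model was limma 3.58.1 with trended and robust empirical Bayes moderation in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the genes tested, and genes with an adjusted p under 0.05 were called. Fold changes on this scale understate those of genes with low RPKM. Every adjusted p of a single gene comes from limma unless another tool is named. Differences between a pair of effects were tested in limma as an interaction contrast over the genes tested in both tables. Overlaps of calls were tested with a one-sided Fisher's exact test. That test takes genes as independent draws, which they are not, so its p-values overstate the evidence for a shared effect. Gene lists, 38 in all, covered lysosome, autophagy, apoptosis, chromatin, cell cycle, stress, RNA processing and markers of other cell types. A list with at least 5 tested members was tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of the comparison, and again with an estimated correlation. With an estimated correlation, camera also rests on the few residual degrees of freedom of the fit. Few lists could pass there whatever their correlation, so a call lost in that setting does not show that members move together. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

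The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the targeted genes, the 8 largest rises and the 8 largest falls with an RPKM of at least 5 in the higher group and no overlap between groups, and 2 to 4 members of each described list with the smallest adjusted p. It also took 5 genes per direction with the largest difference between a pair of effects and 6 genes per direction called alike in a pair of comparisons. Among the 298 genes so named, 175 overlap another annotated gene. With no strand setting stated, reads of such genes and their neighbours cannot be told apart, and near-identical paralogs are likewise uncertain.

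The limma test was run on simulated values with 100 genes changed at each fold. It called 83%, 72%, 82% and 69% of the 2-fold changes in the BEAS-2B, NCI-H1299 TSA, LCDR and hnRNP K tables, on 10152, 9848, 10573 and 9525 genes. At 1.5-fold it called 57%, 43%, 60% and 36%, with 4, 3, 4 and 4 false calls. The simulated noise was independent between genes, and far fewer genes were changed than were called in the data. These rates and false calls need not carry over to the real values. Alternatives changed the pseudocount to 0.1 or 1, the filter to 2 RPKM or none, the scaling to median centring or quantile normalization, and the moderation to its plain form. Others required a log2 fold change of at least 1, left out each library in turn, or added the replicate number as a block. The planned count test was run once on recovered reads, called more genes than limma in every table, and was then left out, since the unit is RPKM, so its values are not given. A limma voom fit on genes with at least 10 recovered reads took its place and was added after the data had been seen, as were a fit without genes that hold certain 3′ UTR words, the list tests without each library or without misplaced members, and the read ratios without each library. Members misplaced in the fixed lists were ALG2, a glycosylation gene taken for PDCD6, which encodes the protein ALG-2 and was also listed, LGMN among membrane proteins, and NPC2 and CREG1 among hydrolases. Their removal changed the call of 1 list, the hydrolases with si-hnRNP K.

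Replicate numbers were shared between treated and control groups, and nothing states that a number marks a common culture or day. In the hnRNP K table, libraries of the same number deviated together from their group means across genes, with correlations of 0.381, 0.225 and 0.159, so the numbers were taken to pair these libraries. The blocked values are given beside the results there whose call they changed. Nothing states that replicates came from separate cultures, so p-values measure only the spread between these samples.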

Results

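The data were 22 RNA-seq libraries in 8 groups. BEAS-2B, an immortalised human bronchial epithelial line, and NCI-H1299, a human lung cancer line that lacks p53, were treated for 24 hours with trichostatin A (TSA), an inhibitor of histone deacetylases, or with its solvent DMSO. There were 3 libraries per group in BEAS-2B and 2 per group in NCI-H1299. In NCI-H1299 the long noncoding RNA LCDR was knocked down with a short hairpin RNA (sh-LCDR, n = 3, against sh-Con, n = 3), and hnRNP K, an RNA-binding protein, with a small interfering RNA (si-hnRNP K, n = 3, against si-NC, n = 3). Reads in genes came to 32.0 to 54.3 M (megareads) per library in BEAS-2B DMSO, 38.5 to 44.9 in BEAS-2B TSA, 32.2 to 42.0 in NCI-H1299 DMSO and 34.2 to 53.8 in NCI-H1299 TSA. The knockdown libraries held 20.6 to 27.9 M reads in sh-Con, 21.3 to 23.4 in sh-LCDR, 33.6 to 34.3 in si-NC and 35.6 to 42.0 in si-hnRNP K. Mitochondrially encoded genes took 5.53 to 7.05% of the reads in sh-Con against 4.53 to 5.09% in sh-LCDR. They took 3.26 to 4.94% in si-NC against 4.90 to 5.70% in si-hnRNP K, ranges that overlap. Their share was also higher with TSA, at 2.47 to 3.23% in BEAS-2B DMSO against 3.81 to 4.29% in BEAS-2B TSA. In NCI-H1299 it was 2.71 to 2.85% in DMSO against 3.21 to 3.36% in TSA.

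The targeted genes and LAPTM5, a lysosomal membrane protein gene that the series title links to LCDR and hnRNP K, were examined first. HNRNPK (ENSG00000165119.20, chromosome 9, 83968083 to 83980616, minus strand) fell with its siRNA from 81.7 ± 4.20 RPKM (SD, n = 3) in si-NC to 19.2 ± 4.68 (n = 3), a log2 fold change of −2.09 (SE 0.18, adjusted p = 0.00118). The mean after knockdown was 0.235 times that of si-NC. LCDR, listed in the tables as LINC00653 (ENSG00000273148.1, chromosome 20, 18794529 to 18796067, plus strand, a lincRNA of 1 exon), fell with its hairpin from 1.37 ± 0.387 to 0.668 ± 0.226 RPKM, a log2 fold change of −0.68 (SE 0.20, adjusted p = 0.0475). This rested on 150 reads in sh-Con and 69 in sh-LCDR, a ratio of depth-scaled reads of 0.504 with a 95% interval of 0.373 to 0.674. The mean in sh-LCDR lay above those of other NCI-H1299 controls, 0.321 RPKM in DMSO and 0.531 in si-NC. Levels were not tested across tables. The limma call on LINC00653 was lost without sh-Con 1 (adjusted p = 0.0962), sh-Con 2 (0.0585), sh-Con 3 (0.0862), sh-LCDR 1 (0.117) or sh-LCDR 3 (0.125), with no filter (0.142) and with quantile normalization (0.0525).

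LAPTM5 (ENSG00000162511.7, chromosome 1, 30732469 to 30757820, minus strand) lay below the filter in all 4 tables, so its reads carry the comparison. In the hnRNP K table it had 125 reads in si-NC and 9 in si-hnRNP K, a ratio of depth-scaled reads of 0.0646 (95% interval 0.0289 to 0.127), or 15.5-fold lower. The ratio was 0.0419 without si-hnRNP K 1 and 0.103 without si-hnRNP K 2. In a fit with no filter its log2 fold change was −0.12 with an adjusted p of 0.0162, or 0.0713 with the replicate block. That call was lost without si-NC 1 (0.0558), si-NC 2 (0.0569), si-hnRNP K 2 (0.0544) or si-hnRNP K 3 (0.0675). On recovered reads, voom gave a log2 fold change of −4.37 (adjusted p = 0.00351). In the LCDR table LAPTM5 had 16 reads in sh-Con and 0 in sh-LCDR, at least 4.87-fold lower against the floor of 3 reads over the group. The ratio of depth-scaled reads had an upper 95% bound of 0.284 from counting error in both groups. The adjusted p was 0.0693 in the fit with no filter and 0.0473 without sh-Con 2. The exact permutation test of RPKM gave p = 0.1 in both knockdown tables, the smallest value that 3 against 3 libraries allow. The NCI-H1299 controls themselves differed, with LAPTM5 at 0.220 reads per M in sh-Con, 0.499 in DMSO and 1.23 in si-NC. Summed reads of 18 other blood cell marker genes with a mean under 0.5 RPKM had a ratio of 0.254 (0.227 to 0.284) in the hnRNP K table, and those of 19 such genes a ratio of 1.02 (0.862 to 1.21) in the LCDR table. Single markers in the LCDR table moved both ways, with HCLS1 going from 12 to 0 reads, VAV1 from 10 to 2 and ARHGDIB from 50 to 17, but PTPRC from 10 to 32 and LCP1 from 6 to 16. The 3′ UTR of LAPTM5 holds the word TGCATAA, which occurred in 13.1% of the genes that fell at least 2-fold with si-hnRNP K and were searched, against 9.28% of other genes.

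With TSA, LAPTM5 reads came to 14 in BEAS-2B DMSO and 45 in BEAS-2B TSA (ratio 3.41, 1.84 to 6.72), and to 37 in NCI-H1299 DMSO and 89 in NCI-H1299 TSA (ratio 2.03, 1.37 to 3.06). In NCI-H1299 the ratio was 4.25 without DMSO 1 and 1.21 without DMSO 2, a range wider than its interval, which covers counting error only. Neither passed the fit with no filter (adjusted p = 0.0781 and 0.486), and that in BEAS-2B passed without TSA 1 (0.0498) or TSA 3 (0.0433) and with voom (0.0179). LINC00653 rose with TSA in BEAS-2B from 0.261 ± 0.127 to 1.1 ± 0.149 RPKM (log2 fold change 1.08, SE 0.13, adjusted p = 0.000377). In NCI-H1299 it rose from 0.321 ± 0.0601 to 0.649 ± 0.00441 RPKM (n = 2 per group, log2 fold change 0.49, SE 0.09, adjusted p = 0.0193), a call lost without DMSO 2 (0.0685), TSA 1 (0.0969) or TSA 2 (0.0962), and with voom (0.0702). With si-hnRNP K, LINC00653 had 83 reads against 75, and its log2 fold change of −0.14 did not pass (adjusted p = 0.448). HNRNPK itself fell with TSA in BEAS-2B from 57.7 ± 3.05 to 31.4 ± 1.29 RPKM (log2 fold change −0.87, SE 0.07, adjusted p = 6.83e-05). In NCI-H1299 HNRNPK went from 59.4 ± 3.70 to 49.0 ± 2.26 RPKM (log2 fold change −0.27, adjusted p = 0.0402), a call lost without DMSO 1 (0.123), DMSO 2 (0.0691), TSA 1 (0.0865) or TSA 2 (0.151) and with plain moderation (0.0619).

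**Figure D1:**
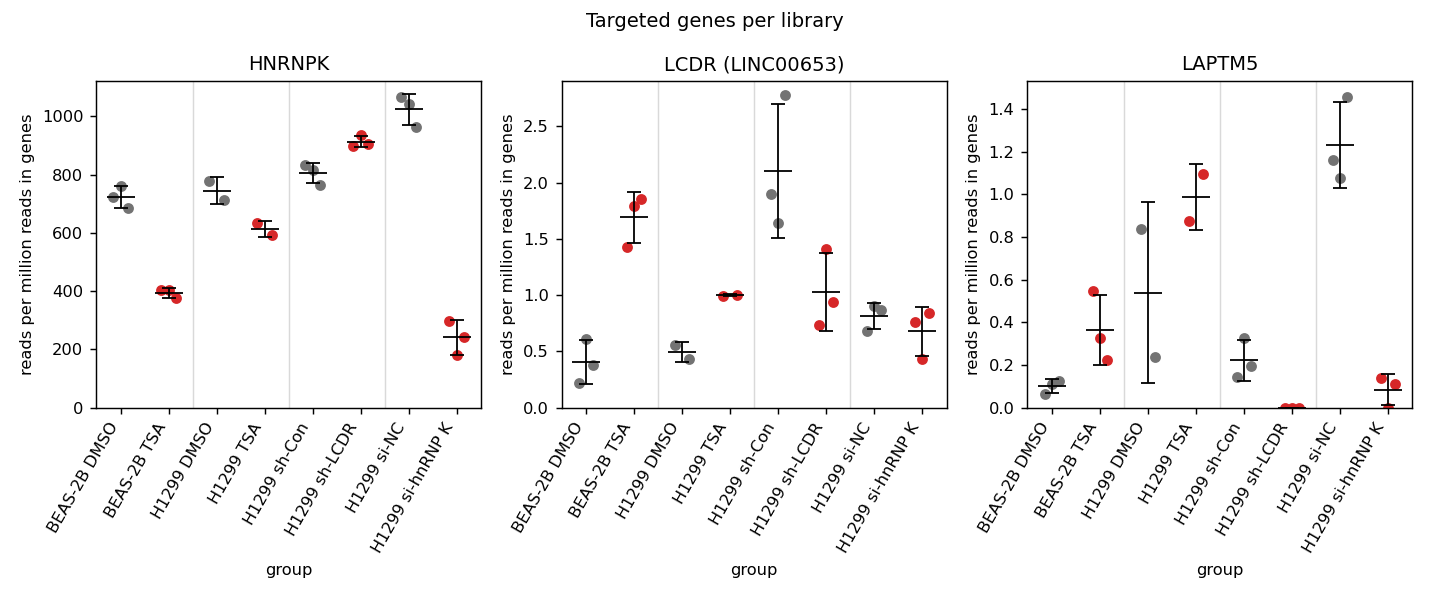
Reads of HNRNPK, LCDR (LINC00653) and LAPTM5 in each library, scaled to depth as reads per M reads in genes, with controls in grey, treated libraries in red, and the mean ± SD of each group. HNRNPK is lowest in the si-hnRNP K libraries, at 181 to 298 reads per M, and LAPTM5 is at 0 in all 3 sh-LCDR libraries.

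The first comparison asked what inhibition of histone deacetylases changed in BEAS-2B. Of 10152 genes tested, 4099 rose and 3091 fell, 70.8% in all. At a preset correlation between genes, lists of neuronal and neuroendocrine genes, metallothioneins, V-ATPase subunits and lysosomal hydrolases rose, while those of the extracellular matrix, of mesenchymal cells and of G2 and mitosis fell. With an estimated correlation no list passed, the smallest adjusted p being 0.166. VGF, which encodes a secreted neuropeptide precursor (ENSG00000128564.6, chromosome 7, 101162509 to 101165593), rose from 0.339 ± 0.0649 to 141 ± 15 RPKM (n = 3 per group, log2 fold change 7.39, SE 0.10, adjusted p = 2.68e-07). KRT7, a simple epithelial keratin (ENSG00000135480.15, chromosome 12, 52232520 to 52252186), fell from 30.2 ± 5.01 to 0.638 ± 0.12 RPKM (log2 fold change −4.75, adjusted p = 9.43e-07).

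Among the other large rises were CEND1 (log2 fold change 4.69), a neuronal differentiation gene, ZCCHC12 (4.59), the cytokine gene TNFSF9 (4.43), PMEL (4.34), known from pigment cells, and the imprinted gene PEG10, from 9.93 ± 0.797 to 221 ± 30.5 RPKM (4.40). MIR7-3HG was listed at 0 in all DMSO libraries and at 10.3 ± 0.552 RPKM with TSA. Large falls included the collagen chaperone SERPINH1 (−4.69), the matrix metalloproteinase MMP14 (−4.64), G0S2 (−3.99), an inhibitor of lipolysis, CCDC9B (−3.94), MARVELD1 (−3.84) and EMP3 (−3.76). All neuronal and neuroendocrine genes measured were called, 17 of 21 higher and 4 lower, with the same counts adjusted over the list alone and a list median of 1.51 (camera adjusted p = 0.00026). SYP, encoding synaptophysin, rose by 3.0, SYT11 by 3.5 and the tubulin gene TUBB4A by 4.12. All 7 metallothionein genes measured, which encode metal-binding proteins, rose, with a median of 2.12 (7 adjusted over the list alone, camera adjusted p = 0.00208). MT1X went from 1.53 ± 0.112 to 47.7 ± 1.64 RPKM and MT1E from 46.2 ± 3.18 to 203 ± 27.9. The adjusted p with an estimated correlation was 0.205 for the neuronal and 0.342 for the metallothionein list.

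Lysosomal genes were a main subject of the series. All 16 V-ATPase subunit genes measured, whose products acidify the lysosome, rose with TSA in BEAS-2B, with a median of 1.03 and 16 higher adjusted over the list alone (camera adjusted p = 0.000287, and 0.166 with an estimated correlation). ATP6V1A went from 0.921 ± 0.103 to 3.36 ± 0.227 RPKM (log2 fold change 1.44), ATP6V0A1 rose by 1.36 and ATP6V1D by 1.21. Of 44 lysosomal hydrolase genes, 32 rose and 5 fell, with the same counts adjusted over the list alone and a median of 0.66 (camera adjusted p = 0.00026, and 0.342 with an estimated correlation). The sialidase gene NEU1 went from 8.26 ± 0.584 to 116 ± 8.89 RPKM (log2 fold change 3.73, SE 0.09), and GM2A, FUCA1 and SCPEP1 rose by 2.22, 2.10 and 1.85. Of 28 lysosomal membrane protein genes, 17 rose and 4 fell (17 and 4 adjusted over the list alone). The median of that list was 0.46 and it did not pass as a list (camera adjusted p = 0.0692, and 0.102 without LGMN). Its member MCOLN1, a lysosomal calcium channel gene, rose from 3.17 ± 0.377 to 12.7 ± 0.541 RPKM. LGMN, which encodes a soluble protease and was listed here as well as among the hydrolases, rose from 1.06 ± 0.0291 to 6.27 ± 0.547 RPKM. In the autophagy machinery, 20 of 30 genes rose and 3 fell (22 and 3 adjusted over the list alone), with a median of 0.54 and a camera adjusted p of 0.0122, or 0.205 with an estimated correlation. ATG2A went from 3.02 ± 0.273 to 18.8 ± 0.994 RPKM, and GABARAPL2 and MAP1LC3B, members of the ATG8 family, rose by 1.33 and 1.05. Genes of the response to lysosomal damage went both ways, 14 higher and 9 lower of 28 (14 and 9 adjusted over the list alone), with CHMP1B at 1.36 and TECPR1 at 0.81 (median 0.19, camera adjusted p = 0.54). Without ALG2, a glycosylation gene that the list held by error, 13 were higher and 9 lower of 27 (13 and 9 adjusted over the list alone, median 0.04, camera adjusted p = 0.652).

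Genes of cell death went both ways. Of 28 pro-apoptotic genes 15 rose and 9 fell (15 and 9 adjusted over the list alone, median 0.28, camera adjusted p = 0.67), among them BMF (1.36), BBC3 (1.37), the death receptor gene TNFRSF10B (0.94) and BOK (−2.16). Of 12 anti-apoptotic genes 2 rose and 6 fell (2 and 6 adjusted over the list alone, median −0.27, camera adjusted p = 0.141), with CFLAR at −1.11, BIRC5 at −1.11 and XIAP at −0.89. Genes of G2 and mitosis fell, 32 of 43 lower and 3 higher, with the same counts adjusted over the list alone and a median of −0.78 (camera adjusted p = 2.99e-07, and 0.334 with an estimated correlation). AURKA, a mitotic kinase gene, went from 9.16 ± 0.68 to 1.58 ± 0.0919 RPKM, and FOXM1, GTSE1 and TPX2 fell by 1.99, 1.55 and 1.32 on the log2 scale.

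Genes of the extracellular matrix fell, 22 of 30 lower and 6 higher (22 and 6 adjusted over the list alone), with a median of −1.17 (camera adjusted p = 3.31e-05, and 0.166 with an estimated correlation). The collagen crosslinker LOX went from 18.5 ± 0.719 to 1.28 ± 0.0791 RPKM and TNC changed by −3.41, whereas CCN2, a secreted matrix-associated factor, rose from 117 ± 3.58 to 672 ± 9.64 RPKM. Of 11 mesenchymal genes 8 fell and 2 rose (8 and 2 adjusted over the list alone, median −1.36, camera adjusted p = 0.00394, and 0.296 with an estimated correlation). The receptor kinase gene AXL went from 31.5 ± 2.24 to 2.28 ± 0.0829 RPKM, TPM1 changed by −2.68 and the transcription factor gene SNAI1 by 1.52. Immediate early genes rose in 19 of 25 cases and fell in 5 (19 and 5 adjusted over the list alone, median 0.82, camera adjusted p = 0.0122, and 0.342 with an estimated correlation), with FOS from 0.473 ± 0.0876 to 13.9 ± 2.49 RPKM, ZFP36 at 2.44 and FOSL1 at −3.18.

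Of 27 hnRNP genes 22 fell and 2 rose (22 and 2 adjusted over the list alone), with a median of −0.71 (camera adjusted p = 1.38e-05, and 0.166 with an estimated correlation), HNRNPUL1 at −1.99, HNRNPL at −1.42 and HNRNPC at −1.30. Of 19 SR splicing factor genes 10 fell and 2 rose (10 and 2 adjusted over the list alone, median −0.34, camera adjusted p = 0.0122, and 0.717 with an estimated correlation), with SRSF4 and SRSF7 both at −1.32. Among the 12 HDAC and sirtuin genes, which include the targets of TSA, 9 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.41, camera adjusted p = 0.141). HDAC3 rose by 1.5 and SIRT4 by 0.90, and the 1 that fell was HDAC7, from 2.79 ± 0.105 to 0.134 ± 0.0203 RPKM. Of 14 histone acetyltransferase and bromodomain genes 9 fell and 2 rose (9 and 2 adjusted over the list alone, median −0.38), with CREBBP at −1.04 and BRD9 at −0.78. That list passed at a camera adjusted p of 0.0358, but not with an estimated correlation (0.296) nor without DMSO 2 (0.0568). Of 43 nuclear genes of oxidative phosphorylation 28 rose and 5 fell (28 and 5 adjusted over the list alone, median 0.43), with NDUFA2 at 1.57, COX6A1 at 1.37 and NDUFB3 at 1.1. Their camera adjusted p was 0.0358, and 0.744 with an estimated correlation, 0.0537 with median centring, 0.0674 without DMSO 2 and 0.0665 without TSA 1.

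Markers of other cell types moved singly in BEAS-2B and were too few for a list test. CORO1A, a gene of blood cells, rose from 1.26 ± 0.205 to 7.65 ± 0.438 RPKM (log2 fold change 2.21), while SRGN and ARHGDIB changed by −1.48 and −1.23. The fibroblast marker COL1A1 fell from 37.0 ± 3.20 to 9.42 ± 0.585 RPKM, and PDGFRB and THY1 changed by −1.36 and −0.61. AGER, a marker of alveolar epithelium, changed by −0.43. The median log2 fold change of all tested genes was 0.11, and with values centred on the median 3566 genes rose and 3592 fell. The groups did not overlap for 74.8% of genes, against 10% by chance.

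The same question was put to NCI-H1299, with 2 libraries per group. TSA raised 1985 and lowered 1330 of 9848 genes tested, or 1562 and 1794 with quantile normalization. At the preset correlation the lists of neuronal genes, replication-dependent histone genes, targets of the antioxidant factor NRF2 and immediate early genes rose, while those of heat shock genes, the unfolded protein and integrated stress responses and interferon-stimulated genes fell. None passed with an estimated correlation, the smallest adjusted p being 0.795. Linker and replication-independent histone genes did not pass as a list (camera adjusted p = 0.633). TTC9B (ENSG00000174521.7, chromosome 19, 40216058 to 40218399) rose from 0.475 ± 0.154 to 11.8 ± 1.2 RPKM (n = 2 per group, log2 fold change 3.66, SE 0.14, adjusted p = 0.00169), and DKK1, a secreted Wnt antagonist, from 1.88 ± 0.12 to 24.1 ± 0.598 (3.37, adjusted p = 0.000968). G0S2 (ENSG00000123689.5, chromosome 1, 209675420 to 209676388) fell from 387 ± 3.39 to 118 ± 4.04 RPKM (log2 fold change −1.70, adjusted p = 0.0011).

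Other large rises were MC5R (3.26), a melanocortin receptor gene, the neuronal activity gene ARC (3.22), ANKRD1 (3.19), BAIAP3 (3.09), the muscarinic receptor gene CHRM4 (2.84) and the kinesin light chain gene KLC3 (2.73). PCBD1 (−1.41), EMP3 (−1.40), APOBEC3C (−1.27), CNN2 (−1.24), CBX5 (−1.23), which encodes a heterochromatin protein, and SERPINH1 (−1.14) were lower. Of 20 neuronal and neuroendocrine genes 14 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.93 (camera adjusted p = 0.000452, and 0.795 with an estimated correlation). The adhesion molecule gene L1CAM rose by 2.04, NPTX2 by 2.08, SYP by 1.75 and CHGA, encoding chromogranin A, by 1.45. Of 18 NRF2 target genes 13 rose and 2 fell (13 and 2 adjusted over the list alone, median 0.39, camera adjusted p = 0.00405, and 0.795 with an estimated correlation), with TXNRD1 from 3.0 ± 0.0874 to 13.3 ± 0.548 RPKM and SRXN1 at 1.75. Of 18 replication-dependent histone genes 9 rose and 1 fell (11 and 2 adjusted over the list alone, median 0.46, camera adjusted p = 0.0159, and 0.795 with an estimated correlation), led by the linker histone gene HIST1H1C, from 56.0 ± 5.06 to 160 ± 7.83 RPKM. Of 25 immediate early genes 14 rose and 2 fell (16 and 2 adjusted over the list alone, median 0.33, camera adjusted p = 0.0159, and 0.795 with an estimated correlation), with EGR1 at 0.85, DUSP1 at 0.72 and MYC at 0.66.

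Heat shock genes fell in 9 of 12 cases with no rise (9 adjusted over the list alone, median −0.41, camera adjusted p = 0.00341, and 0.795 with an estimated correlation). HSPA8, a constitutive chaperone gene, went from 400 ± 39.8 to 191 ± 10.4 RPKM, HSPH1 changed by −1.15 and HSP90AB1 by −0.85. Of 34 genes of the unfolded protein and integrated stress responses 14 fell and 2 rose (17 and 4 adjusted over the list alone, median −0.20, camera adjusted p = 0.0159, and 0.795 with an estimated correlation), with ATF5 at −1.03 and HYOU1 at −0.60. Of 26 interferon-stimulated genes 7 fell and 3 rose (8 and 3 adjusted over the list alone, median −0.19), with IFITM3 from 23.4 ± 0.558 to 10.5 ± 0.0237 RPKM, IFI35 at −1.32 and BST2 at 1.1. This list passed at a camera adjusted p of 0.0301, but not with an estimated correlation (0.795) nor without DMSO 1 (0.0672). Of 22 snoRNA host genes 11 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.30, camera adjusted p = 0.0159), with SNHG9 at 1.45 and SNHG7 at 0.97. The list's p was 0.817 with an estimated correlation and 0.0501 without TSA 1. Ribosomal protein genes and mitochondrially encoded genes passed at a camera adjusted p of 0.0334 each, with medians of 0.14 and 0.26 and with 24 of 73 and 8 of 15 members higher (24 and 9 adjusted over the list alone). The ribosomal list was lost with an estimated correlation (adjusted p = 0.883), with median centring (0.0774) and without DMSO 2 (0.207) or TSA 1 (0.202), and the mitochondrial list with an estimated correlation (0.817), with median centring (0.0522) and without DMSO 1 (0.131) or TSA 2 (0.0805).

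Lysosomal lists did not pass in NCI-H1299. Of 42 hydrolase genes 13 rose and 6 fell (15 and 8 adjusted over the list alone, median 0.11, camera adjusted p = 0.517), with CREG1, which encodes a lysosomal glycoprotein and no hydrolase, at 1.24, MAN2B1 at 0.68, CTSF at 0.63 and NEU1 at 0.63. Of 16 V-ATPase genes 1 rose and 1 fell (1 and 1 adjusted over the list alone, median −0.04, camera adjusted p = 0.517). Of 25 lysosomal membrane protein genes 5 rose and 3 fell (6 and 4 adjusted over the list alone, median 0.14, camera adjusted p = 0.866). The transporter gene ABCA2 went from 1.96 ± 0.148 to 5.89 ± 0.399 RPKM and CD63, an abundant tetraspanin gene, from 144 ± 1.59 to 103 ± 0.424. Of 26 autophagy genes 6 rose and 2 fell (6 and 2 adjusted over the list alone, median 0.07, camera adjusted p = 0.67), with MAP1LC3A at 1.30 and TFE3, a lysosomal transcription factor gene, at −0.47. In the response to lysosomal damage 3 of 25 rose and 1 fell (1 and 0 adjusted over the list alone), or 2 of 24 and 1 without ALG2, with CHMP1B at 0.61. That list's median was 0.02, its camera direction was down and its adjusted p was 0.966, or 0.87 without ALG2. Of 27 pro-apoptotic genes 4 rose and 4 fell (4 and 4 adjusted over the list alone, median 0.05, camera adjusted p = 0.866), and of 13 anti-apoptotic genes 1 rose and 3 fell (1 and 3 adjusted over the list alone, median 0.00, camera adjusted p = 0.549). Of 12 HDAC and sirtuin genes 3 rose and 2 fell (4 and 2 adjusted over the list alone, median 0.13, camera adjusted p = 0.87), and HDAC7 changed by −0.57. Among markers of other cell types CORO1A rose from 1.5 ± 0.069 to 8.65 ± 0.175 RPKM and COL1A1 from 0.144 to 0.736, while CD37, a gene of blood cells, and AGER changed by −0.84 and −0.42. The CD37 call was lost without DMSO 2 (adjusted p = 0.0501), and that of AGER without DMSO 1 (0.0526), DMSO 2 (0.104), TSA 1 (0.142) or TSA 2 (0.12).

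The groups did not overlap for 72.1% of genes, against 33.3% by chance. Calls in NCI-H1299 depended on the filter and the libraries. With no filter limma called 0 of 34046 genes, with all named genes lost, whereas 4571 genes had an unadjusted p under 0.05 in the filtered fit and voom on recovered reads called 4824 higher and 2258 lower. Calls fell to 1093 higher and 617 lower without DMSO 1, 914 and 522 without DMSO 2, 831 and 451 without TSA 1, and 790 and 410 without TSA 2.

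The effects of TSA in both lines were compared over 8297 genes tested in both. Shared rises included BAIAP3 (3.37 in BEAS-2B and 3.09 in NCI-H1299), ENTPD2 (3.15 and 2.87), CHRM4 (3.62 and 2.84), ARC (2.76 and 3.22), CEND1 (4.69 and 2.62) and DHRS2 (4.09 and 2.50). Shared falls included HRCT1 (−1.86 and −2.02), G0S2 (−3.99 and −1.70), TNS2 (−2.04 and −1.63), the immunoproteasome gene PSMB10 (−2.17 and −1.47), PCBD1 (−1.89 and −1.41) and MIR6772 (−2.28 and −1.81), which lies within KIFC3. In all 1007 genes rose in both lines, against 621 for independent lists (odds ratio 3.47, one-sided Fisher's exact p = 7.83e-106), and 711 fell in both, against 376 (odds ratio 4.09, one-sided Fisher's exact p = 1.33e-105). Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.445 and a Spearman rho of 0.394.

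The effect itself differed between the lines for 4669 genes, 2452 with a higher value in BEAS-2B and 2217 with a lower one. VGF rose in both, by 7.39 in BEAS-2B and 2.22 in NCI-H1299 (difference 5.18, SE 0.17, adjusted p = 7.96e-08). FOS changed by 3.88 and 0.24, MT1X by 4.57 and 1.09, PMEL by 4.34 and 0.65, and SNORA80B, which lies within ODC1, by 3.56 and −1.61. On the other side DKK1 changed by −0.71 in BEAS-2B and 3.37 in NCI-H1299 (difference −4.08, adjusted p = 5.01e-07), NOG, a BMP antagonist gene, by −2.95 and 1.12, LOX by −3.41 and 0.54, HOXB2 by −2.94 and 0.73, and MMP14 by −4.64 and −0.96. Of the gene lists, V-ATPase subunits differed with a median of 1.04 (camera adjusted p = 1.04e-05, and 0.0687 with an estimated correlation) and lysosomal hydrolases with 0.55 (camera adjusted p = 5.86e-06, and 0.307 with an estimated correlation), both higher in BEAS-2B.

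**Figure D2:**
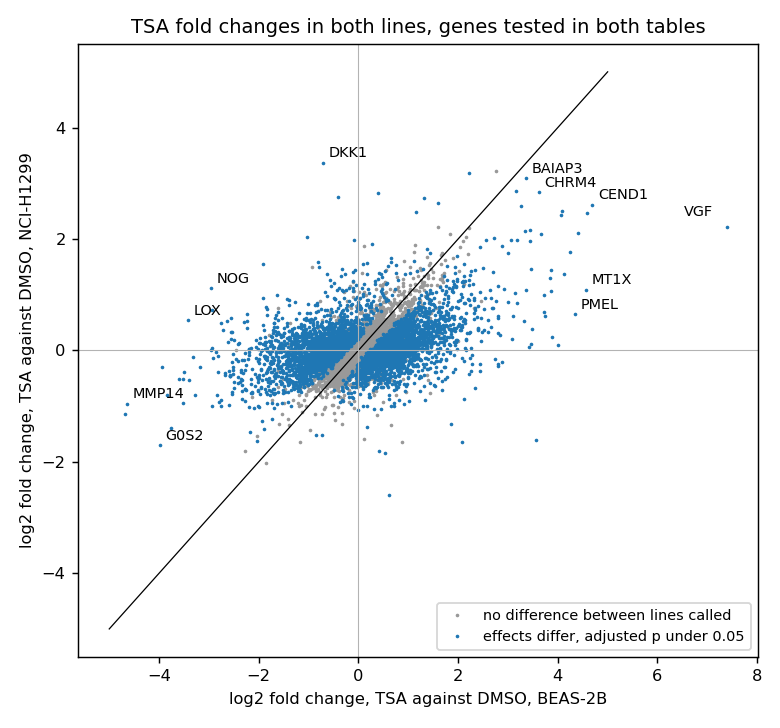
Log2 fold change with TSA in BEAS-2B (x axis) and NCI-H1299 (y axis) for 8297 genes, with the 4669 genes whose effects differed in blue and the line of equal effects drawn. The spread is wider along the BEAS-2B axis, with standard deviations of 0.86 and 0.42.

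The next comparison asked what changed in NCI-H1299 when LCDR was knocked down. Of 10573 genes tested 2005 rose and 1772 fell, but 1857 and 1934 with median centring and 1900 and 1943 with quantile normalization. At the preset correlation the list of interferon-stimulated genes fell and those of hnRNP genes and snoRNA host genes rose. None passed with an estimated correlation, the smallest adjusted p being 0.321, and the snoRNA list did not pass without sh-Con 1 (0.0665). Lysosomal genes went both ways, with falls among them of the cathepsin gene CTSB. MDK, a secreted heparin-binding growth factor gene (ENSG00000110492.15, chromosome 11, 46380756 to 46383837), rose from 5.24 ± 0.618 to 53.1 ± 3.25 RPKM (n = 3 per group, log2 fold change 3.23, SE 0.09, adjusted p = 9.77e-05). TRIM28, a corepressor gene (ENSG00000130726.11, chromosome 19, 58544091 to 58550722), fell from 36.5 ± 1.99 to 3.55 ± 0.321 RPKM (log2 fold change −3.19, SE 0.08, adjusted p = 8.81e-05).

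PEG10 (2.53), UGCG (2.28), which encodes glucosylceramide synthase, MEA1 (2.17), NT5DC2 (2.01) and LINC02434 (1.74) also rose. Large falls were URB1-AS1 (−2.39), DMAC2 (−2.23), CMTM6 (−2.18), EI24 (−1.95), PIP4K2C (−1.88) and MRFAP1, from 221 ± 11.8 to 49.9 ± 1.07 RPKM. The rise of MIR635, a microRNA gene within WIPI1, from 1.27 ± 1.51 to 6.61 ± 3.35 RPKM (adjusted p = 0.0486) was lost without sh-Con 1 (0.129), sh-Con 2 (0.136), sh-LCDR 1 (0.11), sh-LCDR 2 (0.0649) or sh-LCDR 3 (0.131), with a pseudocount of 0.1 (0.0512) and with no filter (0.146). A 7-base word, TCCTGTC, occurred in the 3′ UTRs of 44.5% of the genes that fell at least 2-fold and were searched, against 16.2% of other genes. The 3′ UTRs of TRIM28, DMAC2, EI24 and PIP4K2C hold its 8-base form TCCTGTCA, that of MRFAP1 holds the 7-base word, and that of MDK holds ACACATCA, tied in the same search to higher genes. Those of PEG10, UGCG and MEA1 hold its 7-base form ACACATC alone. CCTGTCA, the word next in rank to TCCTGTC, is in the 3′ UTR of CMTM6, which fell, and in that of PEG10, which rose. The 3′ UTR of CMTM6 also holds CACATCA, the word next in rank to ACACATC.

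Of 40 lysosomal hydrolase genes 17 fell and 9 rose with sh-LCDR (18 and 9 adjusted over the list alone, median −0.08, camera adjusted p = 0.14). CTSB went from 5.6 ± 0.249 to 1.81 ± 0.19 RPKM (log2 fold change −1.41, adjusted p = 0.000291), PLBD2 from 2.63 ± 0.112 to 0.934 ± 0.0607, ACP2 changed by −1.07, and the cathepsin gene CTSC rose by 0.66. Of 26 lysosomal membrane protein genes 3 rose and 3 fell (3 and 2 adjusted over the list alone, median −0.03, camera adjusted p = 0.449), with LAPTM4A, a relative of LAPTM5, at 0.37, ENTPD4 at −0.51 and SLC36A1 at −0.59. Of 16 V-ATPase genes 5 fell and 1 rose (6 and 1 adjusted over the list alone, median −0.09, camera adjusted p = 0.0838), with ATP6V1C1 at −1.41, ATP6V0D1 at −0.59 and ATP6V1D at −0.57. In the response to lysosomal damage 10 of 27 genes fell and 3 rose (10 and 4 adjusted over the list alone, median −0.09, camera adjusted p = 0.0811), or 9 of 26 and 3 without ALG2 (camera adjusted p = 0.123). These included the ESCRT-III genes CHMP7, from 3.80 ± 0.154 to 0.900 ± 0.0946 RPKM, and CHMP1A (−1.33). Of 29 autophagy genes 11 fell and 7 rose (13 and 7 adjusted over the list alone, median −0.11, camera adjusted p = 0.241), with the receptor gene CALCOCO2 at −1.0, ATG4B at −0.99, MAP1LC3B at −0.82 and WIPI2 at 0.54. The 3′ UTRs of SLC36A1, ATP6V1C1 and MAP1LC3B, which fell, and of WIPI2, which rose, hold TCCTGTCA. Those of CHMP7, CHMP1A, ATG4B and ATP6V1D, which fell, and of CTSC, which rose, hold the 7-base word alone. Those of CTSB, ACP2 and CALCOCO2, which fell, hold CCTGTCA, the word next in rank. That of ATP6V1C1 also holds ACACATC, the word tied to higher genes.

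Of 29 pro-apoptotic genes 8 rose and 7 fell (8 and 7 adjusted over the list alone), with ENDOG at 0.74, CASP4 at 0.66, BMF at −1.08 and TP53INP1 at −1.19. The median was 0.01, the camera direction was down and the adjusted p was 0.993. Of 14 anti-apoptotic genes 4 fell and 3 rose (5 and 3 adjusted over the list alone, median −0.12, camera adjusted p = 0.386). The survivin gene BIRC5 went from 10.3 ± 0.57 to 2.59 ± 0.141 RPKM and MCL1 from 61.7 to 35.7, while BIRC3 went from 2.46 to 9.23. The 3′ UTR of MCL1 holds TCCTGTC, those of BIRC5, BMF and RALY, which also fell, hold CCTGTCA, and that of BIRC3 holds ACACATCA. That of MCL1 also holds CACATCA, a word tied to higher genes. Of 23 interferon-stimulated genes 12 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of −0.34 (camera adjusted p = 0.000974, and 0.321 with an estimated correlation). IFIT1 went from 6.52 ± 0.486 to 2.41 ± 0.442 RPKM, IFITM1 changed by −1.58, IFIT3 by −1.13 and HERC5 by −0.98. Of 28 hnRNP genes 16 rose and 2 fell (20 and 2 adjusted over the list alone, median 0.19, camera adjusted p = 0.0121, and 0.321 with an estimated correlation), with HNRNPM at 0.65, HNRNPA2B1 at 0.56 and RALY at −0.54. Of 23 snoRNA host genes 8 rose and 0 fell (8 and 0 adjusted over the list alone, median 0.19, camera adjusted p = 0.027), with SNHG4 at 1.26, DANCR at 1.13 and SNHG7 at 0.77. That list's p was 0.673 with an estimated correlation and 0.0665 without sh-Con 1. Of 11 HDAC and sirtuin genes 1 rose and 3 fell (1 and 4 adjusted over the list alone, median −0.04, camera adjusted p = 0.449), with SIRT2 at 0.37 and SIRT1 at −0.50.

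Of 15 mitochondrially encoded genes 3 fell and 0 rose (0 adjusted over the list alone) and the list passed with a median of −0.23 (camera adjusted p = 0.0431). Its p was 0.673 with an estimated correlation, 0.0502 with median centring, 0.0714 without sh-Con 3 and 0.103 without sh-LCDR 1. None of the markers of other cell types measured here, CD37 (adjusted p = 0.782), FBLN1 (0.374) and AGER (0.2), was called. HNRNPK went from 64.2 ± 2.75 to 72.9 ± 1.57 RPKM with sh-LCDR (log2 fold change 0.18, adjusted p = 0.0399). The HNRNPK call was lost without sh-Con 1 (0.0648), sh-Con 2 (0.102), sh-Con 3 (0.064), sh-LCDR 1 (0.0748), sh-LCDR 2 (0.136) or sh-LCDR 3 (0.0989), with no filter (0.0862), median centring (0.0558) or quantile normalization (0.551). The groups did not overlap for 50.8% of genes, against 10% by chance, and without sh-LCDR 2 the genes called higher numbered 1334.

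The knockdown of hnRNP K in NCI-H1299 was compared with si-NC. Of 9525 genes tested 1447 rose and 1897 fell, so 43.3% of the calls were higher. With quantile normalization 3575 genes were called, 49.4% of them higher. At the preset correlation the lists of cholesterol synthesis, extracellular matrix and interferon-stimulated genes, lysosomal hydrolases and epithelial genes fell, while those of snoRNA host, heat shock and cancer-testis genes rose. None passed with an estimated correlation, the smallest adjusted p being 0.61, and the epithelial list did not pass with the replicate block (0.0562), nor the hydrolases without si-NC 3 (0.0774), si-hnRNP K 3 (0.0632) or the members NPC2 and CREG1 (0.0927). SPP1, which encodes the secreted protein osteopontin (ENSG00000118785.13, chromosome 4, 87975650 to 87983426), rose from 2.87 ± 0.0798 to 27.8 ± 6.13 RPKM (n = 3 per group, log2 fold change 3.05, adjusted p = 0.000736). CCND1, encoding cyclin D1 (ENSG00000110092.3, chromosome 11, 69641087 to 69654474), fell from 59.6 ± 6.33 to 12.7 ± 2.35 RPKM (log2 fold change −2.20, adjusted p = 0.000979).

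The spliceosomal RNA gene RNU5A-1, which lies opposite PARP16, rose from 2.40 ± 1.94 to 23.6 ± 6.48 RPKM (log2 fold change 3.29, SE 0.56, adjusted p = 0.00721). TM4SF1 (2.14), MIR324 (2.02), which lies opposite ACADVL, NFKBIB (2.02), which lies opposite SIRT2, the pseudogene SUMO1P1 (1.95), TMEM147-AS1 (1.62) and NOLC1, a nucleolar protein gene, from 10.4 ± 1.32 to 42.2 ± 0.925 RPKM, rose as well. ATP5F1D, a subunit gene of ATP synthase, fell from 48.8 to 13.1 RPKM and NT5E changed by −1.85. RF02038 and RF02039, which lie opposite SPRY4, changed by −2.86 and −2.17, MIR635 by −1.80 and MIR1208 by −2.20. With no filter these 4 were not called (adjusted p = 0.0556, 0.0797, 0.0863 and 0.152). Without si-NC 1, RF02039 (0.0506), MIR635 (0.0555) and MIR1208 (0.11) were not called, and MIR1208 was not called either without si-NC 2 (0.0654), si-NC 3 (0.0774), si-hnRNP K 2 (0.0615) or si-hnRNP K 3 (0.074) or with a pseudocount of 0.1 (0.0786).

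Cholesterol synthesis genes fell in 17 of 23 cases with no rise (18 lower and 1 higher adjusted over the list alone), with a median of −0.62 (camera adjusted p = 5.4e-06, and 0.61 with an estimated correlation). IDI1 went from 8.56 ± 0.518 to 4.55 ± 0.197 RPKM, HSD17B7 changed by −0.95, ACAT2 by −0.75 and MVD by −0.68. Of 21 extracellular matrix genes 13 fell and 3 rose (13 and 3 adjusted over the list alone, median −0.64, camera adjusted p = 0.00803, and 0.61 with an estimated correlation). MMP9, encoding a secreted gelatinase, went from 1.55 ± 0.0894 to 0.0605 ± 0.00859 RPKM, COL6A1 changed by −1.51 and MMP14 by −1.07, while THBS1 rose by 1.06. Of 18 interferon-stimulated genes 9 fell and 0 rose (11 and 0 adjusted over the list alone, median −0.34, camera adjusted p = 0.00732, and 0.61 with an estimated correlation), with OAS3 at −0.99, IRF1 at −0.72 and STAT2 at −0.63. Of 8 epithelial genes 5 fell and 0 rose (5 and 0 adjusted over the list alone, median −0.60), with the keratin genes KRT15 at −2.09 and KRT8 at −0.97. That list passed at a camera adjusted p of 0.0256 but not with an estimated correlation (0.61), with the replicate block (0.0562) or without si-hnRNP K 1 (0.0526).

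Of 39 lysosomal hydrolase genes 17 fell and 5 rose with si-hnRNP K (19 and 5 adjusted over the list alone, median −0.29). CTSB went from 7.92 to 4.27 RPKM and GALNS changed by −0.97, while PPT1 went from 3.10 to 6.36 RPKM and CTSC rose by 0.64. The hydrolase list passed at a camera adjusted p of 0.0421 but not with an estimated correlation (0.61), without si-NC 3 (0.0774) or si-hnRNP K 3 (0.0632), or without NPC2 and CREG1, which encode no hydrolases (0.0927). Of 25 lysosomal membrane protein genes 9 fell and 3 rose (9 and 3 adjusted over the list alone, median −0.15, camera adjusted p = 0.156), with ABCA2 at −1.14, MFSD12 at −0.81, SCARB2 at −0.70 and CTNS at −0.46. Of 16 V-ATPase genes 3 fell and 2 rose (3 and 2 adjusted over the list alone), with ATP6AP1 at −0.80 and ATP6V0A2 at −0.61. The V-ATPase median was 0.01, its camera direction was down and its adjusted p was 0.797. Of 27 autophagy genes 11 fell and 3 rose (11 and 5 adjusted over the list alone, median −0.12, camera adjusted p = 0.362), with ATG12 at −1.08, MAP1LC3A at −0.88, CALCOCO2 at −0.69 and BECN1, encoding beclin 1, at 0.85. In the response to lysosomal damage 6 of 25 genes fell and 2 rose (8 and 3 adjusted over the list alone, median −0.02, camera adjusted p = 0.609), or 6 of 24 and 1 without ALG2 (camera adjusted p = 0.423), with TECPR1 at −0.87 and the galectin genes LGALS1 and LGALS3 at −0.76 and −0.74.

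Of 29 pro-apoptotic genes 8 fell and 4 rose with si-hnRNP K (8 and 4 adjusted over the list alone, median −0.16, camera adjusted p = 0.44), with TP53INP1 at −1.26, CASP4 at −0.64, FAS at −0.60 and CYCS at 0.78. Of 13 anti-apoptotic genes 6 fell and 2 rose (6 and 3 adjusted over the list alone), with BIRC2 at −1.07, TRAF1 at −1.05, BIRC3 at −0.91 and CFLAR at −0.69. The anti-apoptotic median was 0.06, the camera direction was down and the adjusted p was 0.553. Of 11 HDAC and sirtuin genes 2 rose and 2 fell (4 and 2 adjusted over the list alone, median 0.03, camera adjusted p = 0.609), with HDAC1 and HDAC2 both at 0.36 and HDAC6 at −0.77. Of 23 snoRNA host genes 6 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.39, camera adjusted p = 0.00732, and 0.724 with an estimated correlation), with SNHG7 at 1.29, SNHG11 at 1.20 and SNHG1 from 34.1 to 69.3 RPKM. Of 9 cancer-testis genes 5 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.54, camera adjusted p = 0.00732, and 0.61 with an estimated correlation). MAGEA4 rose from 42.4 to 73.7 RPKM, and MAGEA3 and MAGEA6, near-identical paralogs whose reads are hard to part, by 0.64 and 0.60. Of 13 heat shock genes 5 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.23, camera adjusted p = 0.0236), with HSPD1 at 0.76 and HSPA4 at 0.54. The heat shock list's p was 0.664 with an estimated correlation and 0.0601 without si-hnRNP K 2.

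Of 15 mitochondrially encoded genes 5 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.48, camera adjusted p = 0.00517, and 0.61 with an estimated correlation). MT-ND6 rose by 1.1 (adjusted p = 0.0259), a call lost without si-NC 1 (0.0674), si-NC 2 (0.0821), si-hnRNP K 2 (0.0778) or si-hnRNP K 3 (0.0839) and with no filter (0.105). Of 72 ribosomal protein genes 1 rose and 2 fell (0 and 0 adjusted over the list alone, median 0.12), and the list did not pass (camera adjusted p = 0.0611). It passed with the replicate block (0.019), but not with the block and an estimated correlation (adjusted p = 0.791). Among markers of other cell types, ARHGDIB fell from 0.559 to 0.0854 RPKM, CORO1A from 1.84 to 0.676 and the fibroblast marker FBLN1 by 0.56 on the log2 scale. CD37, another gene of blood cells, went from 0.838 to 0.896 RPKM (adjusted p = 0.90), and AGER did not pass (adjusted p = 0.169). Among the genes named here as lower with si-hnRNP K, the 3′ UTRs of CCND1, NT5E, OAS3, SCARB2, ATG12, TP53INP1 and BIRC2 hold TGCATAA, as that of LAPTM5 does. The groups did not overlap for 50.4% of genes, against 10% by chance. Genes called higher numbered 954 without si-NC 1, 878 without si-NC 2, 936 without si-hnRNP K 2 and 757 without si-hnRNP K 3, and genes called lower 1249 without si-NC 2 and 1247 without si-hnRNP K 3. At this preset correlation 13, 10, 4 and 9 of 34 lists passed in the 4 comparisons in the order given, and with an estimated correlation camera called 0 in each.

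**Figure D3:**
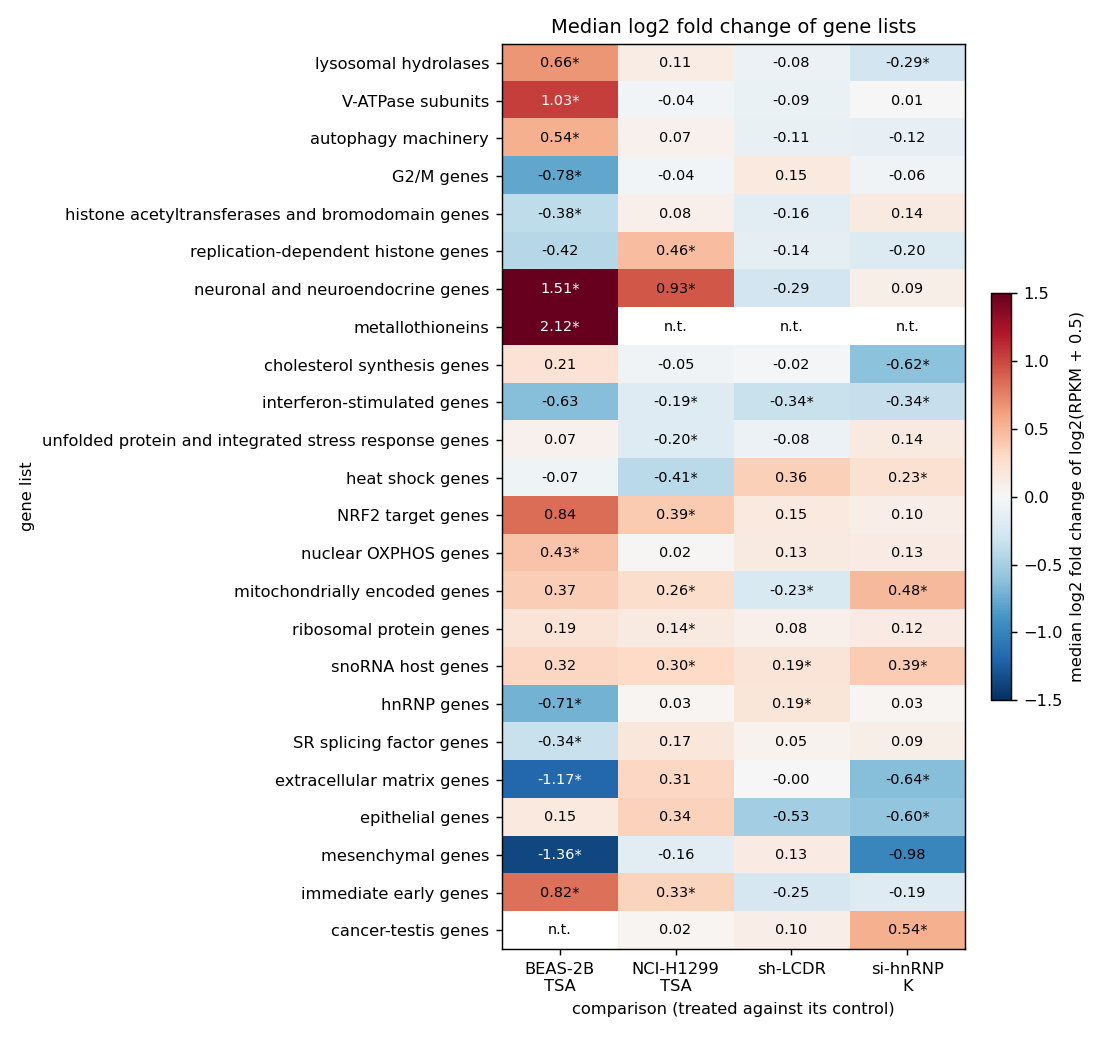
Median log2 fold change of the members of each gene list, for lists that passed camera in at least 1 of the 4 comparisons, with an asterisk where the camera adjusted p at a preset correlation of 0.01 was under 0.05 and n.t. where a list was not tested. V-ATPase subunits stand at 1.03 in BEAS-2B TSA and at −0.04, −0.09 and 0.01 in NCI-H1299 TSA, sh-LCDR and si-hnRNP K.

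The effects of the knockdowns were compared over 8903 genes, since the series title links LCDR and hnRNP K. Both knockdowns raised HMOX1 (1.97 with sh-LCDR and 1.0 with si-hnRNP K), which encodes a heme-degrading stress enzyme, THBS1 (1.23 and 1.06), TPM4 (1.06 and 1.26), TM4SF1 (0.97 and 2.14), RPS27AP13 (0.97 and 0.96) and FAM32A (0.90 and 1.09), whose 3′ UTR holds ACACATCA. Both lowered the urokinase gene PLAU (−1.40 and −1.48), the calcium-binding protein genes S100A3 (−1.41 and −1.62) and S100A2 (−1.24 and −1.08), RRAD (−1.71 and −1.30), CNDP2 (−1.51 and −1.28), whose 3′ UTR holds TCCTGTCA, TGCATAA and CACATCA, and TP53INP1 (−1.19 and −1.26), whose 3′ UTR holds TGCATAA. The genes raised by both numbered 324, against 270 for independent lists (odds ratio 1.32, one-sided Fisher's exact p = 4.71e-05), and those lowered by both 466, against 321 (odds ratio 1.86, one-sided Fisher's exact p = 5.06e-22). In opposite directions 632 genes were called, 405 higher and 227 lower with sh-LCDR, against 359 and 242 for independent lists. Across genes, which are not independent replicates, Pearson's r was 0.0407 and Spearman's rho 0.0635. The same limit holds for the p-values of Fisher's test.

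The effects of the knockdowns differed for 3648 genes, 1999 with a higher and 1649 with a lower value for sh-LCDR. MDK changed by 3.23 with sh-LCDR and −0.61 with si-hnRNP K (difference 3.83, SE 0.13, adjusted p = 2.51e-07), UGCG, whose 3′ UTR holds ACACATC and TGCATAA, by 2.28 and −0.59, CCND1 by 0.52 and −2.20, and ARHGAP33 by 0.96 and −1.72. MIR635 differed too, at 2.22 and −1.80. On the other side were URB1-AS1 (−2.39 and 1.08), MRFAP1 (−2.13 and 0.96), OSTC (−1.80 and 0.62), whose 3′ UTR holds TCCTGTCA, NDUFA8 (−1.57 and 0.86), whose 3′ UTR holds the 7-base word alone, and SPP1, at −0.17 with sh-LCDR (adjusted p = 0.0974) and 3.05 with si-hnRNP K. Mitochondrially encoded genes differed with a median of −0.82 (camera adjusted p = 0.00382, and 0.725 with an estimated correlation). Cholesterol synthesis genes differed with a median of 0.32 and genes of the unfolded protein and integrated stress responses with −0.29 (camera adjusted p = 0.0411 each, and 0.725 each with an estimated correlation).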

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

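Tests chosen after the result was seen were that of a single library and that of counting error, the bounds of single markers, the word in HNRNPK, the left-out word genes, the voom fit and the splits that part every pair. The effects of TSA differed between the lines by the interaction test for 4669 genes. Of the genes called in opposite directions, all 468 also differed by that test. Opposite calls from the same libraries all but ensure this, so it adds no support. Lists that differed by camera at the preset correlation, as medians of BEAS-2B minus NCI-H1299, were V-ATPase subunits (1.04), lysosomal hydrolases (0.55) and autophagy machinery (0.35), all higher in BEAS-2B. Neuronal and neuroendocrine genes (0.92), immediate early genes (0.65) and nuclear genes of oxidative phosphorylation (0.37) were also higher in BEAS-2B. Lower in BEAS-2B were mesenchymal genes (−1.33), extracellular matrix genes (−1.20), G2 and mitosis genes (−0.82), hnRNP genes (−0.67), SR splicing factor genes (−0.58) and histone acetyltransferase and bromodomain genes (−0.46). With an estimated correlation none of these lists passed, the smallest adjusted p being 0.0687, for V-ATPase subunits.

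The wider spread of TSA effects in BEAS-2B, with a standard deviation 2.05 times that in NCI-H1299, was weighed against scaling and noise. With quantile normalization the ratio was 2.06, which argues against differences in the distribution of values between libraries. Median centring left it at 2.05, but a factor per library shifts all log2 values alike, so that value could not test scaling. With the squared standard errors taken off it was 2.13, which argues against replicate noise. A difference between the lines themselves, or in the dose that reached them, stays open, since the dose was not given in the sources used here and nothing else was tested.

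The 173 genes that fell at least 2-fold with sh-LCDR were weighed against sequence matches of the hairpin, a single library and few reads. Among all 7-base words of 3′ UTRs, TCCTGTC had the lowest regression statistic, −17.6, against −6.96 and −5.15 for the lowest words of the TSA comparisons, and its share among the searched falls was 2.76 times that in other genes, where the lowest words of the other comparisons, chosen alike, gave 1.0, 1.34 and 1.41 times. That is what matches of the hairpin in other transcripts would give, and these may account for part of the falls, since 61 of the 137 searched falls hold the word and 83 hold it or CCTGTCA, the word next in rank, while the others stay open, as does an effect of LCDR itself. Leaving out any 1 library kept at least 94.2% of the calls, which argues against a single library, although the genes were chosen from these same libraries. The median fallen gene held 5040 reads in sh-Con, which argues against few reads for most of these genes. That median covers 157 genes, of which 17 held under 100 reads, while reads could not be recovered for 16. The word TCCTGTCA occurs at 2 places in the LCDR transcript. Of noncoding transcripts of like length, 3.33% hold it at least once and 0.0492% at 2 places or more. The hairpin sequence was not given in the sources used here. Rises of at least 2-fold with sh-LCDR were not weighed. Among them the share of ACACATC was 4.61 times that in other genes, a larger ratio than that of TCCTGTC among the falls. Its 8-base form ACACATCA occurs at 0 places in the LCDR transcript. What ties ACACATC to higher genes was not tested, so these rises cannot be credited to the loss of LCDR.

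The fall of LAPTM5 reads in both knockdowns was weighed against blood cells in the control cultures and counting error, as LAPTM5 is best known from blood cells. Reads of 19 other blood cell markers with a mean under 0.5 RPKM had a ratio of 1.02 (0.862 to 1.21) with sh-LCDR, where HCLS1 (12 to 0 reads), VAV1 (10 to 2) and ARHGDIB (50 to 17) were lower, like LAPTM5, while PTPRC (10 to 32) and LCP1 (6 to 16) were higher, and those of 18 markers a ratio of 0.254 (0.227 to 0.284) with si-hnRNP K, where ARHGDIB held 1119 of the 1426 si-NC reads and RAC2 went from 139 to 15 reads (ratio 0.0969), or 0.462 with CD37 and CORO1A added. PTPRC and LCP1, abundant in blood cells, were also higher with si-hnRNP K (0 to 8 and 0 to 10 reads). This goes against blood cells as the whole cause, although RAC2, HCLS1, VAV1 and ARHGDIB leave a part open. The counting bounds of the markers' sum and of LAPTM5 were at least 1.79 times apart. That gap cannot decide the matter, since ARHGDIB dominates the sum with si-hnRNP K. There the RAC2 interval (0.0528 to 0.165) overlaps that of LAPTM5 (0.0289 to 0.127). Of 14 summed markers with reads there, the bounds of 5 lay below a ratio of 1 and those of 4 above it. The intervals cover counting error only, and the highest upper bound of the LAPTM5 ratio was 0.284, which argues against counting error. An effect of either knockdown on LAPTM5 stays open as a hypothesis, as does a match of the siRNA. The LAPTM5 3′ UTR holds TGCATAA, the word most tied to falls with si-hnRNP K (statistic −8.38), as do those of CCND1, NT5E and TP53INP1. Only 21 of the 160 searched falls of at least 2-fold hold the word, 13.1% against 9.28% of other genes, a ratio of 1.41. Its 8-base form TGCATAAA, which the target of an siRNA with that match would hold, occurs in 6 of 11 HNRNPK transcripts. These are isoforms of a single gene, 528 to 2942 bases long, and so give no rate. Of coding transcripts near the length of the longest of them, 3.98% hold it. The siRNA sequence was not given in the sources used here.

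Other splits of the same 6 libraries into groups of 3 gave at most 0 genes in BEAS-2B (7190 with the real split), 3 with sh-LCDR (3777) and 0 with si-hnRNP K (3344), where the real split was the 1 as large among 10, too few for a share under 0.05. For genes whose effect differed between the knockdowns, all 80 splits that part every pair of same-numbered si-NC and si-hnRNP K libraries were fitted, and 2 of them reached 3648. These were the real split and the real groups with si-NC and si-hnRNP K exchanged, where both effects add up (4037). The highest of the rest gave 1613. The 2 splits were 2.5% of the set, a share under 0.05. This argues against libraries without any group effect, but cannot exclude that with groups of 3. Splits also remove the effect of each knockdown itself, so the share cannot test whether these effects differ. This set of splits was chosen after the result had been seen. Among 20 drawn splits that part fewer pairs the highest gave 843.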

How the results depend on the processing

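The tests chosen after the data had been seen were the voom fit, which took the place of the planned count test with edgeR, the fit without word genes, the lists without misplaced members, and the list tests and read ratios without each library. The edgeR test had been run once on recovered reads and had called more genes than limma in all 4 tables before it was left out because the unit is RPKM. Of 335 results on named genes, 330 of them called, 4755 alternative values were computed. Of these 4455 kept direction and side of the threshold, 300 lost the call (112 with no filter) and 0 reversed. Depth limits LAPTM5 and LINC00653, which rest on 0 to 125 and 36 to 215 reads per group.

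With no filter, genes higher in BEAS-2B numbered 7903, genes called in NCI-H1299 0 and 0, and genes with a different TSA effect 9224, while LINC00653 in sh-LCDR kept −0.68 (adjusted p = 0.142). At a filter of 2 RPKM, which tests fewer genes, 2078 and 1798 were called higher and lower in BEAS-2B, 1312 and 1028 with sh-LCDR, and 929 and 980 with si-hnRNP K, and differences numbered 2511 for TSA and 1908 for the knockdowns. A log2 fold change of at least 1, stricter by construction, left 1130 and 906 in BEAS-2B, 345 and 49 in NCI-H1299, 146 and 173 with sh-LCDR, 163 and 205 with si-hnRNP K, and 169 shared genes for TSA and 13 for the knockdowns. By voom, which changed the filter and the scale together, 7144 genes were higher in BEAS-2B, 4824 and 2258 were called in NCI-H1299, 2838 lower with sh-LCDR and 3174 lower with si-hnRNP K, with 3935 and 1237 shared, and LAPTM5 in BEAS-2B passed at 1.65 (adjusted p = 0.0179). On the 8870 genes tested both ways in NCI-H1299 voom called 4079 and the RPKM fit 2975. Camera with an estimated correlation, a weak test with so few libraries, called 0 lists in each of the 4 comparisons. Quantile normalization ended the call of LINC00653 with sh-LCDR (−0.68, adjusted p = 0.0525). Without genes that hold the words 978 were lower with sh-LCDR. Except where named, the cause was not tested.

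With each library left out in turn, calls ran from 3714 to 4130 higher and 2772 to 3171 lower in BEAS-2B, 790 to 1093 and 410 to 617 in NCI-H1299 (a lone library was assumed to vary like the other group), 1334 to 1943 and 1220 to 1746 with sh-LCDR, and 757 to 1707 and 1247 to 2071 with si-hnRNP K. Log2 fold changes ran from −0.82 to −0.51 for LINC00653 with sh-LCDR and from −2.25 to −1.90 for HNRNPK with si-hnRNP K. LAPTM5, with no filter, ran from 0.0196 to 0.0375 in BEAS-2B, 0.0157 to 0.0814 in NCI-H1299, −0.0294 to −0.0191 with sh-LCDR and −0.132 to −0.113 with si-hnRNP K. Its ratio of depth-scaled reads ran from 2.61 to 4.11, from 1.21 to 4.25, stayed at 0, and ran from 0.0419 to 0.103 in the same order, and that of LINC00653 with sh-LCDR from 0.405 to 0.583. Differences ran from 3946 to 4912 for TSA and from 3138 to 3818 for the knockdowns.

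The replicate block gave 4244 higher, 3225 lower and 14 lists in BEAS-2B, 1910, 1267 and 10 in NCI-H1299, and 2166, 1868 and 5 with sh-LCDR, tables in which the numbers were not taken to pair libraries. Correlations of same-numbered libraries were −0.133, 0.247 and 0.209 in BEAS-2B, 0.111 in NCI-H1299, and 0.165, −0.0263 and 0.141 with sh-LCDR, and in the tables with 3 pairs replicate 1 in BEAS-2B and replicate 2 with sh-LCDR did not match their own number best. With the block LINC00653 in sh-LCDR stood at −0.68 (adjusted p = 0.0913). With si-hnRNP K the block gave 2024 higher, 2431 lower and 9 lists, put LAPTM5 at −0.124 (adjusted p = 0.0713), and changed no call of a named gene or list other than those given above. Differences with the block numbered 4955 for TSA and 4513 for the knockdowns, and shared calls 1705 and 1090.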

Other observations

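Tests reported here beyond the planned list tests were the 8-base words and the left-out word genes, chosen after the data had been seen. Some gene lists had called members but did not pass as lists. NF-kB target genes went both ways in every comparison, with 7 of 17 higher and 9 lower with TSA in BEAS-2B (7 and 9 adjusted over the list alone, median −0.70, camera adjusted p = 0.205), 3 and 6 in NCI-H1299 (3 and 6 adjusted over the list alone, median 0.03, camera adjusted p = 0.388), 7 and 5 with sh-LCDR (7 and 6 adjusted over the list alone, median 0.17, camera adjusted p = 0.547) and 4 and 8 with si-hnRNP K (4 and 8 adjusted over the list alone, median −0.20, camera adjusted p = 0.301). Of 21 p53 target genes 12 rose and 7 fell with TSA in BEAS-2B (12 and 7 adjusted over the list alone, median 0.38, camera adjusted p = 0.542). In NCI-H1299 3 of 19 rose and 4 fell (3 and 4 adjusted over the list alone, median 0.05, camera adjusted p = 0.997). The p53 target list did not differ between the lines (median difference 0.15, camera adjusted p = 0.403). Genes of glycolysis and hypoxia had 9 of 29 members higher and 14 lower with TSA in BEAS-2B (9 and 14 adjusted over the list alone, median 0.06, camera adjusted p = 0.345) and 6 of 24 higher and 11 lower in NCI-H1299 (6 and 13 adjusted over the list alone, median −0.19, camera adjusted p = 0.138). Genes of G1 and S phase had 16 of 43 members higher and 17 lower with TSA in BEAS-2B (16 and 18 adjusted over the list alone, median −0.08, camera adjusted p = 0.54), and 13 of 40 higher and 7 lower with sh-LCDR (14 and 7 adjusted over the list alone, median 0.08, camera adjusted p = 0.43). Of 8 genes of CDK inhibitors 4 fell and 1 rose with si-hnRNP K (4 and 1 adjusted over the list alone, median −0.50, camera adjusted p = 0.269).

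The words were chosen from the sh-LCDR fold changes, so the medians of their genes there describe that choice and do not test it. Genes whose 3′ UTR holds TCCTGTCA, 362 in number, had a median log2 fold change of −0.21 (SD 0.49), those with TCCTGTC or CCTGTCA but not the 8-base form (1451) a median of −0.11 (SD 0.45), and those with none of the words (5301) a median of 0.03 (SD 0.35). The word most tied to higher genes was ACACATC, in 38.6% of the 83 searched rises of at least 2-fold against 8.36% of other genes, and the 238 genes with its 8-base form ACACATCA had a median of 0.14. Without the genes that hold TCCTGTC, CCTGTCA, ACACATC or CACATCA, 8052 genes were left, of which 1406 were called higher and 978 lower. Among the 6571 of these tested in both knockdown tables, 246 rose in both, against 194 for independent lists, and 257 fell in both, against 165.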
